A study of Homo sapiens with 12 samples.

How the data were processed

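RNA was measured in 12 libraries of A375, an established human melanoma cell line that carries an activating BRAF mutation. Per the labels, cells were treated for 72 hours with SEL201 at 2.5 µM, OTX015 at 50 nM, both agents together (COMBO), or neither agent (titled UNTREATED, with DMSO, the drug solvent, as the treatment label). SEL201 inhibits the kinases MNK1 and MNK2, which phosphorylate the translation factor eIF4E, and OTX015 inhibits BET bromodomain proteins, which bind acetylated chromatin. Each of the 4 groups has 3 libraries, numbered 1 to 3 in the labels. Per the labels' protocols, stranded poly(A) libraries were sequenced as paired-end reads of 150 bases.

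The authors deposited 1 table of raw counts per gene, with 1 column per library. The submitters' processing notes name FastQC, Trimmomatic, STAR 2.5.4b, SAMtools 1.9, featureCounts, DESeq2 and the genome build hg19, without their roles. The gene annotation, the strand setting of the counting and any filter on genes are not given in the sources used here. The table used here holds 8579 genes, and its mean counts run only from 78.67 to 9158.7, with 98% of genes between 106.5 and 7789. Genes outside this range of levels were not analysed here, and neither, whatever their level, were MYC, BRD2, BRD3, EIF4E, MKNK2, HEXIM1, the ribosomal protein genes and the integrins. Column totals, from 15146071 to 24111541, are totals over these genes and not the sequencing depth. Every CPM value (counts scaled to a common library total) below is relative to these genes, and a change shared by most of them would be removed by the scaling.

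Differential expression was tested with edgeR 4.0.16 in R 4.3.3: TMM scaling, filterByExpr, glmQLFit and glmQLFTest over all 12 libraries with group means only, and Benjamini-Hochberg adjustment over the 8579 genes, at an adjusted p under 0.05. There were 6 contrasts: each agent and COMBO against UNTREATED, COMBO against each single agent, and the interaction, which is the COMBO change minus the sum of both single-agent changes on the log2 scale. Standard errors (SE) are the log2 change divided by the square root of the F statistic. Lists of genes were tested with camera in limma 3.58.1 at an inter-gene correlation of 0.01, with adjustment over the 24 lists that had at least 3 measured members. Contrasts, lists, alternatives and the rule for named genes were fixed before the data were examined.

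The named genes of a contrast are the 8 with the largest rise and the 8 with the largest fall among genes past the threshold, with a mean of at least 5 CPM in a compared group and no overlap between the replicates of the compared groups (not asked of the interaction). Clone-based, antisense and unnamed genes were skipped, and a few genes that met these rules are not given here. TGM2, which the series title names, and the measured genes of drug targets and their partners are given whatever their p, and up to 4 members with the lowest p are named per list. Symbols were used as the table gives them, and 8499 of them matched GENCODE v29, used for gene types, GC content and length only. That annotation is on another build, so no coordinates are printed.

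The labels do not say that replicates came from separate cultures, so p-values measure the spread between these libraries, which may be technical. No library pair within a group looked like 1 library counted again: chi-square per degree of freedom over genes was 6.34 or more. Libraries with the same number deviated from their group means together. The correlation across genes of these deviations was 0.26 to 0.57 in all 18 same-numbered pairs and -0.46 to 0.19 in the other 36 pairs, and all 12 libraries matched their own number best. The numbers therefore appear to pair the samples, from the data and not from the labels. The main fit was fixed before this was seen and does not use the pairing. Counts, p-values, leave-out fits and splits below are unpaired unless the replicate block is named. Leaving out 1 library also unbalances the replicate numbers, so that differences between the numbers can enter an unpaired contrast. A replicate block lowered the biological coefficient of variation from 7.92% to 4.35%, and its values are given where it changes a call or moves a count by over 1.5 times.

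The steps were tested on simulated counts of 8579 genes with 50 genes changed at each of 4 fold changes. For SEL201 against UNTREATED, edgeR recovered 34% of genes changed 1.25-fold, 78% at 1.5-fold, 98% at 2-fold and 100% at 3-fold, with 9 unchanged genes called. For the interaction these shares were 20%, 60%, 86% and 100%, with 5 unchanged genes called. The simulated libraries were drawn independently, without the pairing by number, and far fewer genes were changed than were called against UNTREATED. The shares may therefore differ in the real data. Alternatives were RLE size factors, DESeq2 1.42.0, no filter, a stricter filter, the replicate block, fits of only the compared groups, leaving out each library and, for lists, an estimated correlation, the block and fry. With an estimated correlation camera also tests on the residual degrees of freedom of the fit, so that alternative does not isolate the correlation. An alternative without the 4 number 3 libraries was added after the data were seen. Genes with near-identical copies (KRT81, KRT6B, AKR1C1, histone genes and HLA genes) and EIF4A1, whose locus a readthrough transcript overlaps, have uncertain counts, since the treatment of shared reads is not given in the sources used here.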

Results

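The transcriptome of A375 melanoma cells was compared after 72 hours with the MNK1 and MNK2 inhibitor SEL201, the BET inhibitor OTX015, both agents (COMBO) or neither (UNTREATED), in 3 libraries per group. The series addresses what the combination changes in BRAF-mutated melanoma cells, and its title names TGM2. Total counts over the measured genes were 20346729 to 24111541 in UNTREATED, 16382375 to 22626418 in SEL201, 18917153 to 21834086 in OTX015 and 15146071 to 23247709 in COMBO. Principal component 1 held 72.7% of the variance and placed UNTREATED at -32.5 to -30.1, SEL201 at -9 to -7.2, OTX015 at 11.5 to 13.7 and COMBO at 25.1 to 27.6. Component 2 held 8.8% and set the 4 number 3 libraries (-13.2 to -7.2) apart from the other 8 (1.8 to 7.9).

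TGM2, which encodes tissue transglutaminase, a protein-crosslinking enzyme, fell with each agent and fell further with both. Its level was 699 ± 150 CPM in UNTREATED, 230 ± 48.8 in SEL201, 245 ± 46.2 in OTX015 and 127 ± 22.4 in COMBO (mean ± SD, n = 3). Against UNTREATED, the log2 change was -1.60 with SEL201 (SE 0.18, edgeR adjusted p = 3.2e-05), -1.51 with OTX015 (SE 0.18, adjusted p = 9.1e-06) and -2.47 with COMBO (SE 0.18, adjusted p = 6e-08), a 5.54-fold lower level. COMBO was also below SEL201 (log2 change -0.87, edgeR adjusted p = 0.0016) and below OTX015 (log2 change -0.96, adjusted p = 0.0062). The fall with COMBO was smaller than the sum of both falls by 0.65 on the log2 scale, which was not past the threshold (SE 0.25, edgeR adjusted p = 0.4) but was with the replicate block (log2 0.65, adjusted p = 3e-10). Since the series title names TGM2, its change is not taken here as independent evidence. TGM1, the other measured transglutaminase gene, had a log2 change of -0.01 with COMBO (edgeR adjusted p = 0.98).

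**Figure D1:**
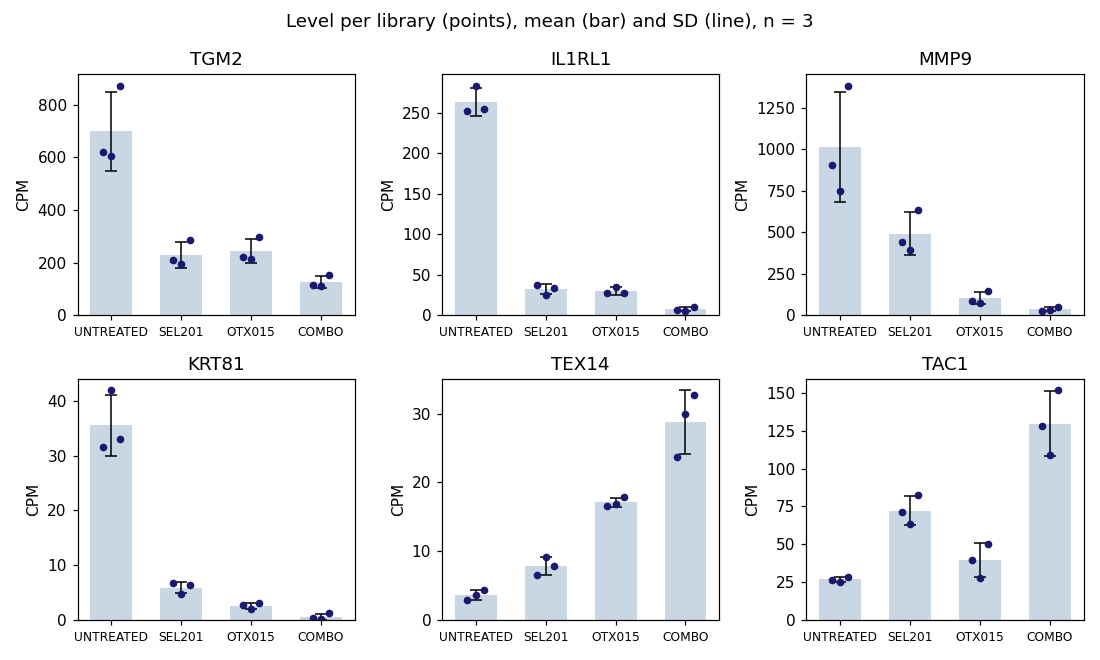
CPM of 6 genes in each group, with 1 point per library, bars at the mean and lines at 1 SD (n = 3). TGM2, IL1RL1, MMP9 and KRT81 were lowest in COMBO, at means of 127, 7.51, 36.9 and 0.56 CPM, and TEX14 and TAC1 were highest there, at 28.8 and 130 CPM.

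SEL201 against UNTREATED asks what SEL201 alone changes, since MNK activity itself was not measured here. SEL201 lowered IL1RL1, the receptor of the cytokine IL-33, from 263 ± 17.6 to 32.1 ± 6.17 CPM, an 8.21-fold fall (log2 change -3.04, SE 0.17, edgeR adjusted p = 1.7e-07). The calcium-binding protein gene CALB1 fell 6.32-fold, the keratin genes KRT81 and KRT7 fell 6.04-fold and 3.6-fold, and the serpin genes SERPINB7 and SERPINB5 fell 4.12-fold and 3.79-fold. AKR1C1, an aldo-keto reductase gene, and TM4SF18 fell 3.67-fold and 3.51-fold. Rises were smaller: TAC1, the substance P precursor gene, rose 2.71-fold, from 26.7 ± 1.81 to 72.3 ± 9.63 CPM (edgeR adjusted p = 7.9e-05). SYT12, a synaptotagmin gene, rose 2.32-fold, NXN 2.28-fold, TEX14 2.18-fold, ATP1B2 2.16-fold, ID4 2.15-fold, PGBD5 2.12-fold and MEGF10 2.04-fold. Among the measured genes of drug targets and their partners, MKNK1, which encodes MNK1, had a log2 change of 0.14 (SE 0.04, edgeR adjusted p = 0.022), and EIF4A1 one of -0.10 (adjusted p = 0.79).

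By list, interferon-stimulated genes fell with SEL201: 9 of 31 measured members were lower and 1 was higher, or 17 and 1 adjusted over the list alone (camera adjusted p = 0.00014; adjusted p = 0.11 with an estimated correlation). IFI44 had a log2 change of -0.64, ISG20 -0.53 and SAMD9 -0.50, while IRF7, an interferon-induced transcription factor gene, rose by 0.66. NF-kB response and cytokine genes fell, with 4 of 12 lower over all genes and adjusted over the list alone (camera adjusted p = 0.014; 0.11 as the adjusted p with an estimated correlation), among them PTGS2 (-0.82), CSF2 (-0.55) and CSF1 (-0.49). Genes of the invasive melanoma state fell in 5 of 10 members, 6 adjusted over the list alone, such as DKK1 (-1.14) and NUAK1 (-0.80), with a camera adjusted p of 0.016 and an adjusted p of 0.11 with an estimated correlation. Extracellular matrix genes fell in 3 of 7 members, also 3 adjusted over the list alone: LOXL4 (-1.12), COL6A3 (-1.10) and COL1A1 (-0.73), with a camera adjusted p of 0.022 (adjusted p = 0.11 with an estimated correlation). Histone genes with polyadenylated transcripts rose in 4 of 9 members, 8 adjusted over the list alone (camera adjusted p = 0.0045; adjusted p = 0.31 with an estimated correlation), and neuronal and synaptic genes rose in 5 of 13 with 1 lower, the same numbers adjusted over the list alone (camera adjusted p = 0.044; adjusted p = 0.12 with an estimated correlation). TUBB3 rose by 0.58 and SYT1 by 0.47 in that list, while the kinesin gene KIF1A fell by 1.15. Of 4 measured epithelial markers, KRT7 (-1.85), KRT14 (-0.98) and CLDN4 (-0.63) were lower, 3 also adjusted over the list alone (camera adjusted p = 0.00084; adjusted p = 0.11 with an estimated correlation).

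In all, edgeR called 867 genes higher and 953 lower with SEL201, of which 12 and 108 changed at least 2-fold. With the replicate block the counts were 1541 and 1639. MEGF10 was not past the threshold without SEL201 replicate 1 (edgeR adjusted p = 0.055) or 2 (0.052), and the change of MKNK1 was not without UNTREATED replicate 1 (0.062) or 3 (0.058) or SEL201 replicate 2 (0.099), when only the compared groups were fitted (0.07) or without the 4 number 3 libraries (0.054).

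OTX015 against UNTREATED asks what OTX015 alone changes. OTX015 lowered the keratin genes KRT7 14.9-fold and KRT81 14-fold, and MMP9, the gelatinase B gene, from 1010 ± 329 to 102 ± 36.3 CPM, or 9.92-fold (log2 change -3.31, SE 0.30, edgeR adjusted p = 8.2e-07). SEMA5A, a semaphorin gene, fell 10.3-fold, the receptor phosphatase gene PTPRB 9.78-fold, the cytokine gene IL37 9.66-fold, FST, which encodes the activin antagonist follistatin, 8.77-fold and IL1RL1 8.75-fold. TEX14 rose 4.77-fold, SYT12, a synaptotagmin gene, 4.13-fold and NXN 4.01-fold. TBX10 rose 3.82-fold, SESN3, a sestrin gene, 3.49-fold, SOD3, the extracellular superoxide dismutase gene, 3.44-fold and AFAP1L2 3.38-fold. MKNK1 rose by 0.38 on the log2 scale (SE 0.04, edgeR adjusted p = 3.4e-06). EIF4A1 had a log2 change of 0.16 (edgeR adjusted p = 0.57, 0.043 with the replicate block). That change was 0 without OTX015 replicate 3 and 0.368 without UNTREATED replicate 3. EIF4A1 was highest in the number 3 library of every group (61.03 CPM in UNTREATED, 56.83 in SEL201, 64.34 in OTX015 and 77.41 in COMBO). Leaving out 1 of these therefore unbalances an unpaired contrast, and the change with the replicate block was 0.165.

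All 9 measured histone genes rose with OTX015, over all genes and adjusted over the list alone (median log2 change 1.01), among them HIST1H2BC (1.40), HIST1H2BD (1.20), HIST1H2BJ (1.15) and HIST1H2AC (0.90), with a camera adjusted p of 0.00016 and an adjusted p of 0.23 with an estimated correlation. SERPINI1, the measured member of the BET-inhibitor response markers, rose by 1.21 (edgeR adjusted p = 4.5e-05). Interferon-stimulated genes fell in 25 of 31 members with 3 higher, or 26 and 3 adjusted over the list alone (median -0.62; camera adjusted p = 8.3e-08; adjusted p = 0.054 with an estimated correlation). OAS2 changed by -1.36, IFI44 by -1.20, ISG20 by -1.01 and SAMD9 by -0.52, and the 3 that rose were IRF7 (1.03), STAT2 (0.21) and IFI6 (0.17). NF-kB response and cytokine genes fell in 10 of 12 members, also 10 adjusted over the list alone (median -0.68; camera adjusted p = 0.00075; adjusted p = 0.054 with an estimated correlation), such as PTGS2 (-1.61), the chemokine gene CCL2 (-1.55) and CSF1 (-1.05). Antigen presentation genes fell in 7 of 12 members, 8 adjusted over the list alone (camera adjusted p = 0.0038; adjusted p = 0.4 with an estimated correlation), led by CTSS (-1.59) and PSMB8 (-0.69). Invasive-state genes fell in 7 of 10, also 7 adjusted over the list alone (camera adjusted p = 0.044; adjusted p = 0.21 with an estimated correlation), led by DKK1 (-1.40) and NUAK1 (-1.32). Neuronal genes rose in 9 of 13 with 2 lower, the same adjusted over the list alone (camera adjusted p = 0.016; adjusted p = 0.12 with an estimated correlation). TUBB3 rose by 0.95 and NLGN1 by 0.78, and KIF1A fell by 2.01. All 4 epithelial markers fell, also 4 adjusted over the list alone (camera adjusted p = 0.0023; adjusted p = 0.12 with an estimated correlation): KRT7 (-3.90), KRT14 (-1.56), CLDN4 (-0.93) and MUC1 (-0.60).

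OTX015 raised 1998 genes and lowered 2117 by the edgeR test, 74 and 374 of them at least 2-fold. The list of CDK inhibitor and senescence genes did not pass the threshold with all libraries (camera adjusted p = 0.16) but did with the replicate block (0.024) and without the 4 number 3 libraries (0.022), and not with an estimated correlation (0.38).

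**Figure D2:**
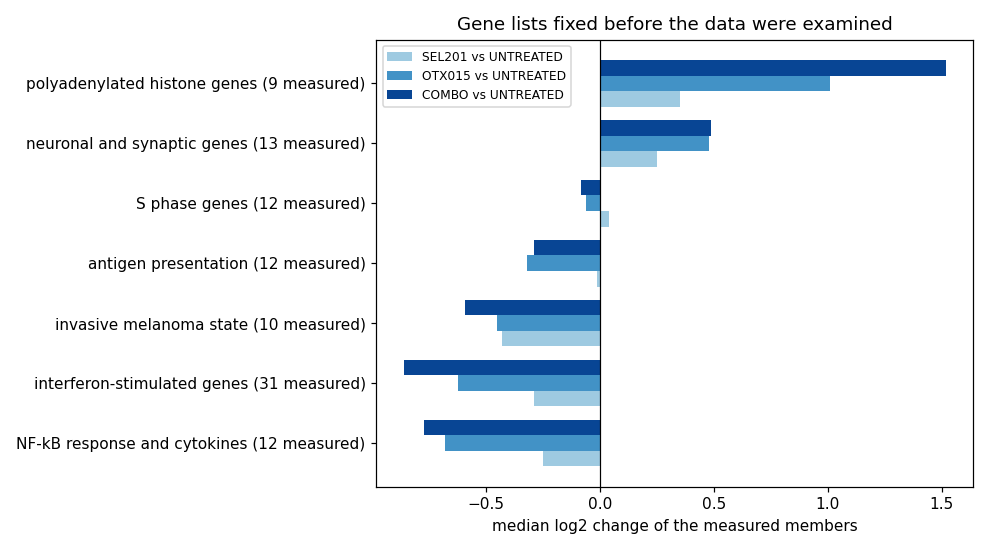
Median log2 change of the measured members of fixed gene lists with each treatment against UNTREATED. Bars show medians over genes, without error bars. The histone medians were 0.35, 1.01 and 1.52 for SEL201, OTX015 and COMBO, and those of interferon-stimulated genes were -0.29, -0.62 and -0.86.

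The single agents changed many genes in the same direction. Both raised 768 genes and both lowered 871, where 202 and 235 would be shared by independent lists of these sizes. In simulated data all libraries were drawn without effects and without the pairing, with a simulated UNTREATED group common to both agents. There the shared calls were 0 and 0, which is no baseline, since groups without effects give almost no calls. Only 7 genes raised by SEL201 were lowered by OTX015, and 2 lowered by SEL201 were raised by OTX015. With the replicate block the shared calls were 1313 and 1408. Across all measured genes, which are not independent replicates, the log2 changes of both agents correlated at r = 0.857, against a mean of 0.492 in the simulated unchanged groups, with a covariance of 0.117 against 0.00707. The simulated groups hold no effects, and 3 UNTREATED libraries cannot be divided into parts of at least 2 each, so part of the excess in shared calls may come from these common libraries. COMBO against SEL201 uses no UNTREATED library. With it, SEL201 alone shared 595 raised and 691 lowered genes, against 163 and 203 for independent lists, and 16 and 16 went the opposite way. The SEL201 libraries enter these 2 contrasts with opposite sign, which works against sharing.

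**Figure D3:**
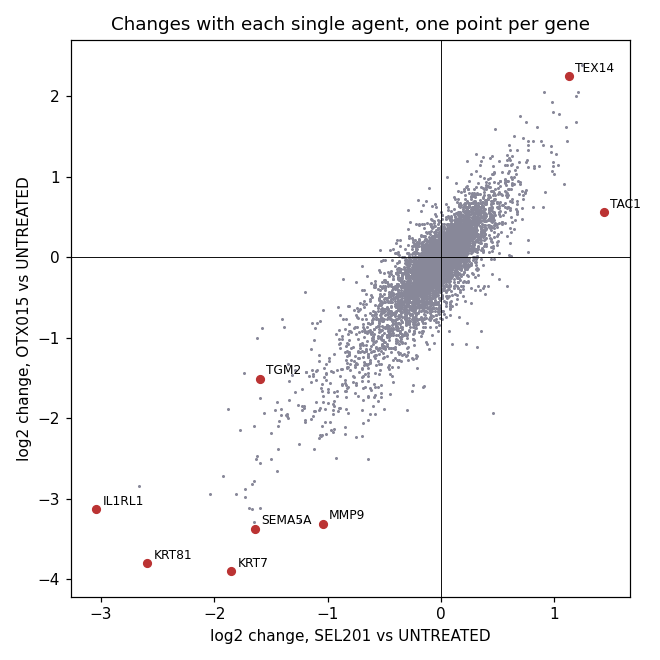
Log2 change with SEL201 (horizontal) and OTX015 (vertical) against UNTREATED, with 1 point per gene and some named genes in red. IL1RL1 fell alike with both, at -3.04 and -3.13, while MMP9 fell by 3.31 with OTX015 and by 1.04 with SEL201.

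COMBO against UNTREATED asks what both inhibitors change together. The lowest gene was KRT81, from 35.5 ± 5.6 to 0.56 ± 0.546 CPM, a 71.3-fold fall (log2 change -6.16, SE 0.34, edgeR adjusted p = 3.9e-09) that rests on 5 to 18 counts per COMBO library (log2 change -7.145 without COMBO replicate 3). IL1RL1 fell 36-fold, KRT7 35-fold, MMP9 27.9-fold, IL7R, the interleukin-7 receptor gene, 18.9-fold, KRT80 15.9-fold, the myosin gene MYO7B 14.5-fold and CALB1 13.8-fold. Counts per COMBO library were also low for KRT7 (13 to 21), MYO7B (14 to 28) and CALB1 (20 to 52). The log2 change of CALB1 ran from -4.23 without COMBO replicate 3 to -3.363 without COMBO replicate 1. TEX14 rose 8-fold, NXN 6-fold, SYT12 5.64-fold, SESN3 5-fold, EFR3B 4.99-fold, TBX10 4.87-fold and TAC1 4.86-fold. MKNK1 rose by 0.51 (SE 0.04, edgeR adjusted p = 9.8e-08). EIF4A1 had a log2 change of 0.30 (edgeR adjusted p = 0.24, 0.00036 with the replicate block and 0.027 without the 4 number 3 libraries). That change was 0.069 without COMBO replicate 3 and 0.512 without UNTREATED replicate 3, fits that leave the number 3 libraries unbalanced. It was 0.299 with the replicate block and 0.278 without the 4 number 3 libraries.

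All 9 histone genes rose with COMBO, also 9 adjusted over the list alone (median 1.52; camera adjusted p = 6.9e-05; adjusted p = 0.2 with an estimated correlation). Interferon-stimulated genes fell in 25 of 31 with 3 higher, or 27 and 3 adjusted over the list alone (median -0.86; camera adjusted p = 6.3e-07; adjusted p = 0.074 with an estimated correlation), with IFI44 at -1.84, ISG20 at -1.49 and SAMD9 at -0.79, and IRF7 at 1.44. NF-kB response and cytokine genes fell in 10 of 12, also 10 adjusted over the list alone (camera adjusted p = 0.0018; adjusted p = 0.074 with an estimated correlation), with CCL2 at -2, CSF2 at -1.93, CSF1 at -1.31 and CXCL3 at -1.04. Neuronal genes rose in 9 of 13 with 2 lower, the same adjusted over the list alone (camera adjusted p = 0.042; adjusted p = 0.18 with an estimated correlation), with TUBB3 at 1.37, NLGN1 at 0.94 and KIF1A at -2.80. Of the 4 epithelial markers 3 were lower, 4 adjusted over the list alone (camera adjusted p = 0.0073; adjusted p = 0.18 with an estimated correlation). Antigen presentation genes were lower in 8 of 12, but the list did not pass (camera adjusted p = 0.058; 0.072 with the replicate block). With the replicate block the invasive-state list (camera adjusted p = 0.057 without the block, 0.011 with it) and the CDK inhibitor and senescence list (0.078 and 0.019) also passed, as they did without the 4 number 3 libraries (0.016 each), but not with an estimated correlation (adjusted p = 0.2 and 0.31). In these lists NUAK1 fell by 1.54 and CDKN1C, a CDK inhibitor gene, by 1.42. In all, edgeR called 2426 genes higher and 2536 lower with COMBO, 174 and 584 of them at least 2-fold.

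COMBO against SEL201 asks what OTX015 adds to SEL201. MMP9 fell 13.5-fold, from 491 ± 128 to 36.9 ± 13.8 CPM (log2 change -3.76, SE 0.32, edgeR adjusted p = 9.2e-07), KRT81 11.8-fold on 5 to 18 counts per COMBO library (log2 change -3.56, and -4.55 without COMBO replicate 3), KRT7 9.72-fold, the zona pellucida gene ZP4 7.6-fold, IL7R 5.87-fold, KRT80 4.81-fold, SEMA6B 4.51-fold and IL1RL1 4.39-fold. The fall of KRT7 rests on 13 to 21 counts per COMBO library. EFR3B rose 4.02-fold, TEX14 3.67-fold, EDIL3 2.66-fold, HIST1H2BD 2.64-fold, NXN 2.63-fold, SESN3 2.52-fold and TBX10 2.47-fold. MKNK1 rose by 0.37 (edgeR adjusted p = 8e-06), and EIF4A1 had a log2 change of 0.40 (adjusted p = 0.15; 1.9e-05 with the replicate block). In fits that leave the number 3 libraries unbalanced, the change of EIF4A1 was 0.606 without SEL201 replicate 3 (edgeR adjusted p = 0.044) and 0.169 without COMBO replicate 3 (0.56). It was 0.372 without the 4 number 3 libraries (edgeR adjusted p = 0.0088) and 0.398 with the replicate block. All 9 histone genes rose, also 9 adjusted over the list alone (camera adjusted p = 6e-06; adjusted p = 0.19 with an estimated correlation). Interferon-stimulated genes fell in 24 of 31 with 2 higher, or 25 and 3 adjusted over the list alone (camera adjusted p = 1.6e-07; adjusted p = 0.062 with an estimated correlation), led by GBP1 (-1.27), IFI44 (-1.20) and CMPK2 (-1.02). NF-kB response and cytokine genes fell in 8 of 12, also 8 adjusted over the list alone (camera adjusted p = 0.0025; adjusted p = 0.083 with an estimated correlation), with CCL2 at -1.58. Antigen presentation genes fell in 7 of 12, 8 adjusted over the list alone (camera adjusted p = 0.0081; adjusted p = 0.42 with an estimated correlation), with CTSS at -1.53. Epithelial markers fell in 3 of 4, also 3 adjusted over the list alone (camera adjusted p = 0.0081; adjusted p = 0.19 with an estimated correlation). The CDK inhibitor and senescence list did not pass with all libraries (camera adjusted p = 0.069) but did with the replicate block (0.012) and without the 4 number 3 libraries (0.011), and not with an estimated correlation (0.34), with CDKN1C at -1.13. OTX015 added to SEL201 raised 1615 genes and lowered 1823 by the edgeR test.

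COMBO against OTX015 asks what SEL201 adds to OTX015. TAC1 rose 3.31-fold, from 39.3 ± 11.3 to 130 ± 21.6 CPM (log2 change 1.72, SE 0.18, edgeR adjusted p = 6.9e-05), and IL1RL1 fell 4.12-fold, from 30 ± 4.53 to 7.51 ± 2.65 CPM (log2 change -2.04, SE 0.20, adjusted p = 4.1e-05). EFR3B rose 2.04-fold, the transcription factor gene MAF 1.79-fold, SOCS1, a suppressor of cytokine signalling, 1.74-fold, TEX14 1.68-fold, HPGD 1.66-fold, ST8SIA5 1.62-fold and SNAI2 1.6-fold. MMP9 fell 2.81-fold, the melanosome transport gene MLPH 2.23-fold, IL7R 2.19-fold, ARHGDIB 2.14-fold, ANKRD1 2.11-fold, the potassium channel gene KCNJ12 2.08-fold and KRT80 2.03-fold. MKNK1 had a log2 change of 0.13 (edgeR adjusted p = 0.062; 0.0064 with the replicate block, 0.032 with DESeq2 and 0.038 without SEL201 replicate 2), and EIF4A1 one of 0.15 (adjusted p = 0.76). Histone genes rose in 6 of 9, also 6 adjusted over the list alone (camera adjusted p = 2.5e-05; adjusted p = 0.27 with an estimated correlation), with HIST1H2AC at 0.43. Interferon-stimulated genes fell in 3 of 31 with 1 higher, or 4 and 2 adjusted over the list alone (camera adjusted p = 0.005; adjusted p = 0.27 with an estimated correlation), with IFI44 at -0.64 and IRF7 at 0.42. The CDK inhibitor and senescence list fell in 2 of 7, also 2 adjusted over the list alone, such as CDKN1C (-0.61), with a camera adjusted p of 0.046 (adjusted p = 0.27 with an estimated correlation). Epithelial markers fell in 2 of 4, 3 adjusted over the list alone (camera adjusted p = 0.011; adjusted p = 0.055 with the replicate block and 0.27 with an estimated correlation), namely CLDN4 (-0.63) and KRT14 (-0.53). The NF-kB response and cytokine list did not pass with all libraries (camera adjusted p = 0.16) but did without the 4 number 3 libraries (0.04), and not with an estimated correlation (0.3).

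SEL201 added to OTX015 raised 249 genes and lowered 344 by the edgeR test, or 861 and 1047 with the replicate block. The number raised was lower without any 1 of the 6 OTX015 and COMBO libraries, in fits that were unpaired and unbalanced in replicate number. It ran from 106 without OTX015 replicate 2 to 156 without COMBO replicate 2. The number lowered was 208 without OTX015 replicate 1, 198 without OTX015 replicate 2, 199 without COMBO replicate 1 and 223 when only the compared groups were fitted. HPGD, SNAI2, SOCS1, KRT80, MMP9 and ANKRD1 each missed the threshold when some single libraries were left out: MMP9 and ANKRD1 without COMBO replicate 1 (adjusted p = 0.058 for both), and SOCS1 without OTX015 replicate 2 (0.076) or COMBO replicate 3 (0.064). HPGD missed it in 10 of 12 such fits (edgeR adjusted p up to 0.17, without COMBO replicate 3), SNAI2 in 7 (up to 0.17, without COMBO replicate 1) and KRT80 in 4 (up to 0.14, without COMBO replicate 1). HPGD also missed it when only the compared groups were fitted (0.087) and without the 4 number 3 libraries (0.19).

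The effect of SEL201 was in this way measured with and without OTX015 in separate libraries. Of the 249 genes raised on top of OTX015, 194 were also raised by SEL201 alone, where independent lists would share 25.2, and of the 344 lowered 271 were also lowered by SEL201 alone, against 38.2. Across genes, which are not independent replicates, the changes correlated at r = 0.691, and the corresponding value for OTX015 without and with SEL201 was 0.906. COMBO stood beyond UNTREATED and both single agents, in the same direction, for 223 higher and 319 lower genes, or 687 and 867 with the replicate block. Leaving out any 1 of the OTX015 and COMBO libraries gave 98 (without OTX015 replicate 2) to 141 (without COMBO replicate 2) higher genes. The lower genes numbered 200 without OTX015 replicate 1, 192 without OTX015 replicate 2 and 191 without COMBO replicate 1.

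The interaction asks whether COMBO differs from the sum of both single-agent log2 changes. The complement receptor gene C3AR1 was 22.4 ± 0.149 CPM in UNTREATED, 8.21 ± 0.787 in SEL201, 3.59 ± 0.644 in OTX015 and 3.88 ± 0.488 in COMBO, 1.57 above the sum on the log2 scale (SE 0.21, edgeR adjusted p = 0.0087). Also above the sum, with edgeR adjusted p in brackets, were AKR1C1 by 1.35 (0.03), SPP1, which encodes osteopontin, by 1.13 (0.011), FST by 1.10 (0.03), KRT6B by 1.08 (0.011), NNMT, a nicotinamide methyltransferase gene, by 1.06 (0.046) and the protocadherin gene PCDH9 by 0.86 (0.00066). Below it were COL2A1 at -0.85 (0.048), TBX2 at -0.73 (0.011), LMO2 at -0.52 (0.033), SOBP at -0.47 (0.03), SESN3 at -0.47 (0.033) and RORB at -0.44 (0.022). Most of these calls ended in some of the 12 fits that leave out 1 library: COL2A1, LMO2 and SESN3 in 11 each, NNMT in 10, FST in 9, SOBP in 8, AKR1C1 in 7, RORB in 6 and SPP1 and TBX2 in 1 each, with edgeR adjusted p up to 0.14 (COL2A1 and NNMT). C3AR1, KRT6B and PCDH9 passed in all 12, and COL2A1 also missed the threshold with RLE size factors (edgeR adjusted p = 0.05), as did LMO2 without the 4 number 3 libraries (0.13). These leave-out fits did not use the replicate block, with which all 24 interaction calls were kept. The edgeR test called 18 genes above and 6 below the sum, and in all 24 the difference was opposite in sign to the summed single-agent changes (526 of 579 with the replicate block), a direction that errors shared with the sum also favour. MKNK1 (-0.01, adjusted p = 0.99) and EIF4A1 (0.25, adjusted p = 0.9) were not past the threshold, and neither was any list (787 genes had an unadjusted p under 0.05).

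The number of interaction calls depended on the fit: 345 and 234 with the replicate block, which also passed 7 lists, and 87 and 32 with DESeq2. The camera adjusted p with the block was 0.0036 for the invasive melanoma state (0.063 without it), 0.012 for interferon-stimulated genes (0.07), 0.022 for p53 targets (0.07) and 0.03 for epithelial markers (0.063). It was 0.047 for S phase genes (0.07), NF-kB response and cytokine genes (0.12) and endothelial and fibroblast genes (0.07). The direction was below the sum for S phase genes and above it for the other lists. With an estimated correlation none of the 7 lists passed, at a camera adjusted p of 0.64 for p53 targets, 0.41 for S phase genes and 0.3 for the other 5. The fits that leave out 1 library are unpaired and unbalanced in replicate number, which may contribute to their lower counts. Without UNTREATED replicate 2 the interaction calls fell to 4 and 0. The genes above the sum numbered 8 without UNTREATED replicate 3, 6 without SEL201 replicate 1 or 2, 7 without OTX015 replicate 1 or COMBO replicate 2 and 10 without COMBO replicate 1. Those below the sum were 1 to 3 without UNTREATED replicate 1 or 3, SEL201 replicate 1 or 2, OTX015 replicate 1 or 3 or COMBO replicate 1 or 2.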

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

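The tests of explanations below were fixed before their results were seen, and the breakdown of the interaction splits was chosen after. The interaction is listed here because the effect of SEL201 differed between cells with and without OTX015 by a test of that difference. It called 18 genes above the sum of the single-agent changes and 6 below. The log2 differences were 1.57 for C3AR1, 1.35 for AKR1C1, 1.13 for SPP1, 1.1 for FST, 1.08 for KRT6B, 1.06 for NNMT and 0.86 for PCDH9, and -0.85 for COL2A1, -0.73 for TBX2, -0.52 for LMO2, -0.47 for SOBP, -0.47 for SESN3 and -0.44 for RORB.

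Across genes, COMBO changes were on average smaller in size than the summed single-agent changes, among genes with a positive and with a negative sum. With the 3 replicate numbers used separately for the COMBO change, the sum and an instrument, which removes errors shared between the estimates, the mean slope was 0.835 (0.824 to 0.855 in 6 assignments), so shared errors alone, which would give a slope near 1, are argued against. A floor that lowered genes reach is a candidate explanation that stays open by the rule fixed beforehand. Genes with a positive sum had a mean slope of 0.855 (0.796 to 0.953), where 1 of the 6 assignments gave 0.953. Genes with a negative sum had a mean slope of 0.826 (0.816 to 0.842). On average the shortfall was therefore not confined to lowered genes. A biological limit common to both agents remains untested.

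SEL201 exposure was reassigned within the libraries with and without OTX015, and 10 of 100 drawn splits, the real one included, called as many genes as the 24 of the real split, with 2401 as the highest other. Chance is not excluded by this share, but the share overstates it, and the splits leave the question open. The splits with many calls follow from how SEL201 exposure was reassigned. All 9 others with 24 or more genes carry part of the SEL201 effect into the contrast, and a full swap on one side carries most. The highest counts were 0, 37, 875 and 2401 where that effect had a weight of 0, 0.67, 1.33 and 2. The 39 drawn splits that carry none of it called 0 genes with edgeR, but they also mix treated and untreated libraries within a group, which widens the spread, so they do not exclude chance either. The splits also ignore the pairing of the libraries, with which the interaction called 345 and 234 genes.

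SEL201 and OTX015 changed genes in the same direction. The UNTREATED libraries they share are argued against as the whole cause: with changes taken from separate libraries, in 6 assignments, the mean correlation across genes was 0.731 (0.712 to 0.749), and the observed covariance exceeded the simulated one by 0.11. A trend on GC content or length, tested on 8499 genes, is argued against too, since the correlation was 0.855 before and 0.859 after its removal. Both technical explanations tested were argued against, so a response common to both inhibitors is a hypothesis these values are consistent with, found and tested on the same data.

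The number 3 libraries stood apart from numbers 1 and 2 in every group. A difference in total counts over the measured genes is argued against, since after thinning all libraries to 15146071 counts the lowest correlation among number 3 pairs was 0.452, against 0.474 before. The sequencing depth itself is not known here. Removing a trend on GC content and length left it at 0.485. A shared day or culture passage may underlie the pairing, but the labels name none, and no biological explanation was tested.

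For the pairwise contrasts, the 6 libraries allow 10 splits, too few for a share under 0.05. In each contrast 1 split, the real one, gave the real number of genes when only those libraries were fitted: 1587 for SEL201 and 3976 for OTX015 against UNTREATED, 4759 for COMBO against UNTREATED, 3135 for COMBO against SEL201 and 408 for COMBO against OTX015. The highest other split called 0 genes by edgeR in every contrast, among the splits that part all 3 pairs and among the others. At an unadjusted p under 0.05 the highest other split had 544, 257, 184, 334 and 714 genes in that order, against 2763, 4598, 5196, 3917 and 1698 in the real split. Splits that mix the groups also widen the spread.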

How the results depend on the processing

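The alternative without the 4 number 3 libraries was chosen after seeing the data; the others were fixed before. Counts moved by over 1.5 times, always upward, with the replicate block: SEL201 against UNTREATED 1541 and 1639, COMBO against OTX015 861 and 1047, the interaction 345 and 234, COMBO beyond both agents 687 and 867, and shared calls 1313 and 1408. DESeq2 gave 87 and 32 interaction genes and the fit without number 3 libraries 57 and 15. Fitting only the compared groups, with fewer libraries, lowered 223 genes in COMBO against OTX015. Other causes were not tested. Leaving out single libraries gave 106 to 276 genes higher and 198 to 371 lower for COMBO against OTX015, 4 to 18 and 0 to 5 for the interaction (0 without UNTREATED replicate 2), and 98 to 243 and 191 to 341 for COMBO beyond both agents; the other counts stayed within 1.5 times. The interaction of TGM2 passed with the replicate block (0.65, adjusted p = 3e-10) and without number 3 libraries (0.652, 0.00085). With an estimated correlation 0 lists passed in any contrast. At the preset correlation 7, 7, 5, 5 and 4 passed, in the order SEL201, OTX015 and COMBO against UNTREATED, COMBO against SEL201 and COMBO against OTX015. This loss is not due to correlation alone. The NF-kB list had an estimated correlation of 0.01, the preset value, and its camera adjusted p with OTX015 still went from 0.00075 to 0.054. Correlation can contribute in other lists that passed with OTX015. The estimate was 0.396 for antigen presentation, 0.395 for histone genes and 0.182 for epithelial markers, far above the preset value. It was 0.045 for interferon-stimulated genes, 0.021 for the invasive state and -0.034 for neuronal genes. The fry test, which does not compare with other genes, passed 12, 19, 18, 17 and 8 lists. In the interaction 0 lists passed, 7 with the replicate block and 2 without number 3 libraries, where the other contrasts had 8, 8, 7, 6 and 5 in the same order. Of 106 single-gene values, 105 kept their call with RLE size factors, 105 with DESeq2, 102 with the block and 101 without number 3 libraries, and 88 of 90 with only the compared groups fitted. Leaving out single libraries kept 1165 of 1272, and no call past the threshold reversed. Some values not past it changed sign, such as EIF4A1 with SEL201 (log2 change -0.101, and 0.11 without UNTREATED replicate 3). That fit leaves the number 3 libraries unbalanced. The filters removed no gene, so they test nothing. The block ended 2 calls in COMBO against UNTREATED and 2 in COMBO against SEL201, and beyond the counts above it changed no list or named gene call other than those given with the results. A table limited to mid-level genes leaves low and very high genes open.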

Other observations

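Beyond the lists that passed, single members moved against or apart from their list. These genes were chosen after their values were seen. EGR1 and FOS, immediate early genes in the MAPK output list, rose with SEL201 (log2 change 1.01 and 0.67), OTX015 (1.28 and 1.12) and COMBO (1.78 and 1.67), while EPHA4 fell (-0.47, -0.65 and -0.69), and that list was not past the camera threshold in any contrast. GDF15, a stress cytokine gene in the p53 target list, fell by 1.36, 1.95 and 2.87, while SESN2, from the same list, rose by 0.21, 0.14 and 0.32. In the pigmentation list MLPH fell (-1.38, -0.87 and -2.02), as did GPNMB (-0.57, -0.74 and -1.06), and S100B rose (0.37, 0.75 and 0.94). All of these had an edgeR adjusted p under 0.05.

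Few cell cycle genes were measured, 12 of 45 S phase and 6 of 54 G2/M genes. Of the 12 S phase genes, 1 was higher and 0 lower with SEL201, 1 higher and 4 lower with OTX015, and 1 higher and 5 lower with COMBO, with medians of 0.04, -0.06 and -0.08. In COMBO against SEL201, 7 were lower and 0 higher (median log2 change -0.15, camera adjusted p = 0.065). E2F8 fell by 0.41 with COMBO and CHAF1B rose by 0.24. Of the 6 G2/M genes 1 was higher and 2 lower with COMBO. Neither list passed the camera threshold in any contrast without the replicate block. The lists of neural crest-like state, TGF-beta response, cholesterol synthesis, fatty acid synthesis, unfolded protein response, hypoxia and glycolysis, lysosome, oxidative phosphorylation, BCL2 family and endothelial and fibroblast genes did not pass there either, with all 12 libraries; the endothelial and fibroblast list passed for SEL201 without the 4 number 3 libraries (camera adjusted p = 0.046).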
